A study of Arabidopsis thaliana with 3 samples.

How the data were processed

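Total RNA of the water and flg22 leaf samples was extracted with a plant RNA column kit and made into Illumina libraries, per the labels' protocols. The submitters' processing notes name Bowtie, an aligner of short reads, and the genome build TAIR10 for these samples, and the build TAIR9 for the small RNA sample. The version of the aligner and the program that counted the reads are not given in the sources used here.

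One table of the whole series was given, which the authors deposited as unnormalized counts per transcript for the water and flg22 samples. The heading of each of its columns of values was compared, in Python 3.11.15, with the title, description, source name and characteristics of every sample, as whole values and as single words. The 2 columns of values matched no sample and were not used. The match was repeated under 3 other rules, chosen after seeing the data. Only the header of the table was read, so the depth of the libraries is not given. No scaling, filter or test was applied to the counts. Before the data were examined, a comparison by scaled count ratios with counting intervals, a set of gene lists and a rule for naming genes had been fixed. None of these was run.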

Results

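The series holds 3 samples of leaf RNA from Arabidopsis thaliana of the Col-0 ecotype, the accession whose genome serves as the species reference. In 2 of them, polyadenylated transcripts were sequenced from leaves of plants aged 5 weeks. One of these leaf samples had been infiltrated with water and the other with flg22 at 1 µM, and both were taken after 6 h. The peptide flg22 is a conserved stretch of bacterial flagellin that plants perceive through the receptor kinase FLS2. The remaining sample is a small RNA library from leaves of plants aged 6 weeks, for which the labels name no treatment.

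The design implies 1 comparison, of transcript levels in flg22-infiltrated against water-infiltrated leaves, with n = 1 library per treatment. No value of this comparison is reported here. The count table of the series has 2 columns of values, headed N and T, and neither heading occurs among the labels of the water or the flg22 sample. The letters can be read as abbreviations, but nothing in the labels or in the header of the table gives their meaning. A gene higher in one column could therefore not be said to be higher or lower after flg22. Assigning the columns from the levels of known flg22-responsive genes would have fixed the direction of those genes in advance. The direction of all other genes would have rested on that assignment. For these reasons neither column was assigned to a treatment. No fold change, gene count or gene group was computed, and values that need no direction were left out as well. The small RNA library was not analysed here.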

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

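None of the alternatives fixed before the data were examined was run, because no column of counts was assigned to a treatment. The result that was recomputed is the number of columns matching no single sample, under 3 settings that were all chosen after seeing the data. It was 2 with whole label values alone, a count fixed in advance because the first match had already searched those values. It was also 2 with the protocols, the names of the characteristics and the series text searched as well. With each heading taken as the first letter of a label word, it was again 2. Under the last setting, N began no label word of any sample, and T began a label word in all 3 samples and so told none apart. No paired analysis was possible because each treatment has 1 library and the result comes from no test.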
